A study of Mus musculus with 6 samples.

How the data were processed

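The series holds 6 RNA-seq libraries of mouse hypothalamus, 3 wild type and 3 SRC-1 knockout. Total RNA was extracted with RNeasy columns and libraries were made with Illumina TruSeq chemistry, per the labels' protocols. Whether RNA was selected by poly(A), and whether the kit kept strand, are not given in the sources used here.

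The authors deposited 1 table of raw counts of read pairs per gene, with no normalization. Reads were aligned with STAR 2.7.10a, per the submitters' processing notes. Counting used featureCounts over exons, grouped by gene, per the file headers. The version is 2.0.0 in the file header and 2.0.3 in the submitters' processing notes, a difference that was not resolved. The command in the header set neither strand, multi-mapping nor multi-gene options, so reads from overlapping genes on both strands cannot be told apart and reads that map to several places or genes were not counted. Genes come from the RefSeq annotation of mm39, the UCSC name of GRCm39, per the file headers. Values of genes with near-identical copies are therefore uncertain. Among the genes named with a change, exons shared with another gene covered 58% of Pmch, 33.3% of Nefm, 25.1% of Gfap, 21.6% of Txnip, 20.1% of Evi2a, 18.2% of Map3k6, 15.9% of Bcas1, 15.7% of Nefh and 13% of Per2 and of Serinc2, and under 10% of any other.

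The table has 50559 genes, 0 rows without a gene name and 0 unused columns of values. Columns were matched to samples by the library codes that the column names and the labels share. Totals ran from 36613507 to 46755553 counts. No 2 libraries of a group matched within sampling noise, with a chi-square per degree of freedom between 8.97 and 19.1 for pairs of the same group, so all were kept as replicates. Pairs across the groups ran from 15.2 (wild-type 2 with knockout 2) to 37.5 (wild-type 1 with knockout 1), so the 2 ranges overlapped.

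The comparison used edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default expression filter by group (a minimum count of 10), robust dispersion and quasi-likelihood F-tests, and Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of F. The common biological coefficient of variation was 12.3%. Levels are TMM-normalised CPM, counts scaled to library size, with SD over 3 libraries. Single values in groups of 3 against 3 cannot reach an exact permutation p under 0.1, so no such tests were made.

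Gene lists, 44 in all, were fixed before the data were examined, as were the design, the alternatives and the rule for named genes. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, adjusted over the 43 lists with at least 5 tested members. Counts are also given adjusted over the list alone. Some genes are on several lists, such as Rax, Foxo1, Fos, Crym and Dcn, so the lists are not separate results. After the results were seen, 6 further lists were added, and a pars tuberalis and a tanycyte list were computed and dropped, since they held genes picked from these results or shared with the ependymal list. Genes were named by a rule with 4 parts. The first was a focus panel of 26 genes. The next was the 12 largest rises and 12 largest falls among genes past the threshold, with at least 1 CPM on average, groups that did not overlap, and a symbol that is not a clone, pseudogene or bare identifier. A part for the case of fewer than 10 such genes was not needed, and the last took up to 4 members with the lowest p per list. Ncoa1 counts under the first and the next. Cnp, Tshb, Gh, Txnip, Epcam, Nnat, Magel2 and the genes of chromosome 12 and their relatives other than Ncoa1, Pomc and Adi1 were chosen after their values were seen. Some genes that the rule or a list would name are withheld and not reported here.

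Genes near Ncoa1 were those on its chromosome within 10 Mb by the table's own coordinates, compared with all other tested genes by Fisher's exact test. Alternatives were size factors by RLE, library totals alone, no filter, a filter of at least 1 CPM in at least 3 libraries, each library left out in turn, a replicate block, DESeq2 1.42.0, limma-voom with and without sample quality weights, other thresholds, gene sets and windows, an estimated correlation and fry. A fit without the wild-type and the knockout library with most growth hormone counts, and a window of 30 Mb, were added after seeing the data.

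Pseudogenes and genes that rose by over 1 on the log2 scale were matched with blastn 2.17.0 to protein-coding transcripts of GENCODE, with at least 60% coverage and 90% identity. This search was also designed after seeing the data, and it replaced a search of the whole genome that was too slow to finish.

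Tests were checked on simulated counts for this comparison, with the real means, depths and dispersions, over 19877 genes. Genes were drawn independently of each other, and those set to change had at least 1 CPM in wild type. Recovery of lower genes, or with spread shared between genes, was therefore not checked. edgeR recovered 73.1% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 97% of those changed 4-fold, with 15 false calls among 183. DESeq2 made 38 false calls among 211, limma-voom 13 among 181 and limma-voom with sample quality weights 14 among 182. Counts from DESeq2 may therefore hold more false calls than those from the other tools. Camera called both simulated lists of changed genes and 0 of 20 unchanged lists, with the preset and with an estimated correlation. Fry called both and 1 of the 20. Members of the simulated lists varied independently, whereas estimated correlations of the real lists ran from -0.046 (choroid plexus) to 0.79 (myelin). The simulation therefore does not check the preset correlation for lists whose members vary together.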

Results

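Total RNA from the hypothalamus was sequenced in 6 mouse libraries, 3 from wild-type animals and 3 from animals lacking SRC-1. SRC-1, steroid receptor coactivator 1, is a p160 coactivator of nuclear receptors and is encoded by Ncoa1. The deposited counts summed to 40371284, 36613507 and 42191925 for wild-type replicates 1 to 3, and to 42743082, 39341074 and 46755553 for knockout replicates 1 to 3. Of 50559 genes in the table, 20257 had enough counts to be tested. The labels do not say that the replicates are separate animals, so the p-values measure the spread between these samples, which may be technical. All 6 libraries carried 979 or more counts of Uty, a gene of the Y chromosome, and at most 11 counts of Xist, the RNA of the inactive X.

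The first question was whether the deleted gene was lower in the libraries labelled as knockout. Ncoa1 (chromosome 12, 4297362 to 4569452, minus strand, GRCm39) fell from 126.5 ± 3.94 CPM in wild type to 38.8 ± 1.54 CPM in the knockout (counts scaled to library size; SD, n = 3 each), a 3.26-fold difference. The log2 fold change was -1.71 ± 0.065 (SE) with an adjusted p of 1.87e-06 in edgeR's quasi-likelihood test, the lowest of all genes tested. Counts were 5180, 4630 and 5406 in wild type and 1692, 1478 and 1766 in the knockout, so every library matched its label. The counts cover all exons of the gene together, and which part was deleted is not in the labels. The related coactivators Ncoa2 (-0.01 ± 0.066) and Ncoa3 (0.10 ± 0.11) did not pass, with adjusted p of 0.982 and 0.804.

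The comparison of the genotypes asked which genes depend on SRC-1 in the hypothalamus. Loss of SRC-1 went with 169 changed genes, 49 higher and 120 lower in the knockout. The named falls included genes of cilia and of tanycytes, the cells of the ventricle floor. On the log2 scale, Sntn, a protein of the ciliary tip, fell (-2.81 ± 0.48, SE), as did Cfap52 (-1.74 ± 0.30) and Spag16, part of the axoneme (-1.71 ± 0.24). Rax, a homeobox gene that marks tanycytes, fell from 2.96 ± 1.20 to 0.595 ± 0.0563 CPM, and the collagen gene Col23a1 from 54.9 ± 16.4 to 15.8 ± 0.904 CPM (SD, n = 3 each). The named rises included genes of oligodendrocytes. Opalin rose from 17.6 ± 2.09 to 35.3 ± 5.11 CPM, and Mbp, myelin basic protein, from 1923 ± 234 to 3118 ± 507 CPM. With 1 library left out in turn, Opalin passed in 6 of 6 fits, Rax and Spag16 in 5, Sntn and Col23a1 in 2, and Cfap52 and Mbp in 1. Mbp passed without knockout replicate 3 (adjusted p 0.0298), with 0.126, 0.0849, 0.0735, 0.158 and 0.0722 without wild-type 1 to 3 and knockout 1 and 2. Cfap52 passed without knockout 2 (0.0291), with 0.0731, 0.0522, 0.0623, 0.0959 and 0.0843 without wild-type 1 to 3 and knockout 1 and 3. Sntn had 0.115, 0.0899, 0.11 and 0.102 without wild-type 1, wild-type 2, knockout 1 and knockout 3, and Col23a1 0.076, 0.169, 0.102 and 0.107 without wild-type 2 and knockout 1 to 3.

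The other named falls, all past the adjusted threshold, were Cyp2f2, a cytochrome P450 (-3.67 ± 0.53), the carboxylesterase Ces1d (-3.39 ± 0.40), Stoml3 (-2.43 ± 0.40), the adenylate kinase Ak9 (-1.84 ± 0.34), Serinc2 (-1.67 ± 0.27) and Corin, a protease that activates natriuretic peptide (-1.60 ± 0.23). The other named rises were Tbr1, a transcription factor of cortical projection neurons (2.26 ± 0.24), Samd3 (2.03 ± 0.32), Amd2 (2.01 ± 0.30), Tmem88b (0.87 ± 0.14), Enpp6 (0.85 ± 0.15), Tmem125 (0.78 ± 0.13), Galnt6 (0.76 ± 0.13), Aspa, which cleaves N-acetylaspartate in oligodendrocytes (0.76 ± 0.13), Adi1, an enzyme of methionine salvage (0.75 ± 0.099), and Evi2a (0.73 ± 0.13). In the same 6 fits Tbr1 and Adi1 passed in 6, Amd2 and Corin in 5, Serinc2 in 4, Samd3, Enpp6, Tmem125, Aspa, Ces1d and Stoml3 in 3, and Tmem88b, Galnt6, Evi2a, Cyp2f2 and Ak9 in 2. Amd2 is uncertain because its exons match Amd1 at 99.6% identity, and Ces1d and Cyp2f2 belong to families of similar genes.

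The 169 calls came from edgeR with Benjamini-Hochberg adjusted p under 0.05, and 2625 genes had an unadjusted p under 0.05. In all 169 the groups did not overlap, as in 17.6% of all genes tested, where chance gives 10%. The count was 69 without wild-type replicate 1, 36 without knockout replicate 1, 260 without knockout replicate 2 and 29 without both first replicates, the pair with the most growth hormone counts. It was 66 with library totals alone, 84 with the stricter filter, 821 with DESeq2, 473 with limma-voom using sample quality weights and 966 with no filter. The excess of falls did not hold throughout, since without knockout replicate 3 there were 123 higher and 89 lower, against 36 higher and 224 lower without knockout replicate 2. With 1 library left out, rises ran from 13 to 123 and falls from 23 to 224.

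**Figure D1:**
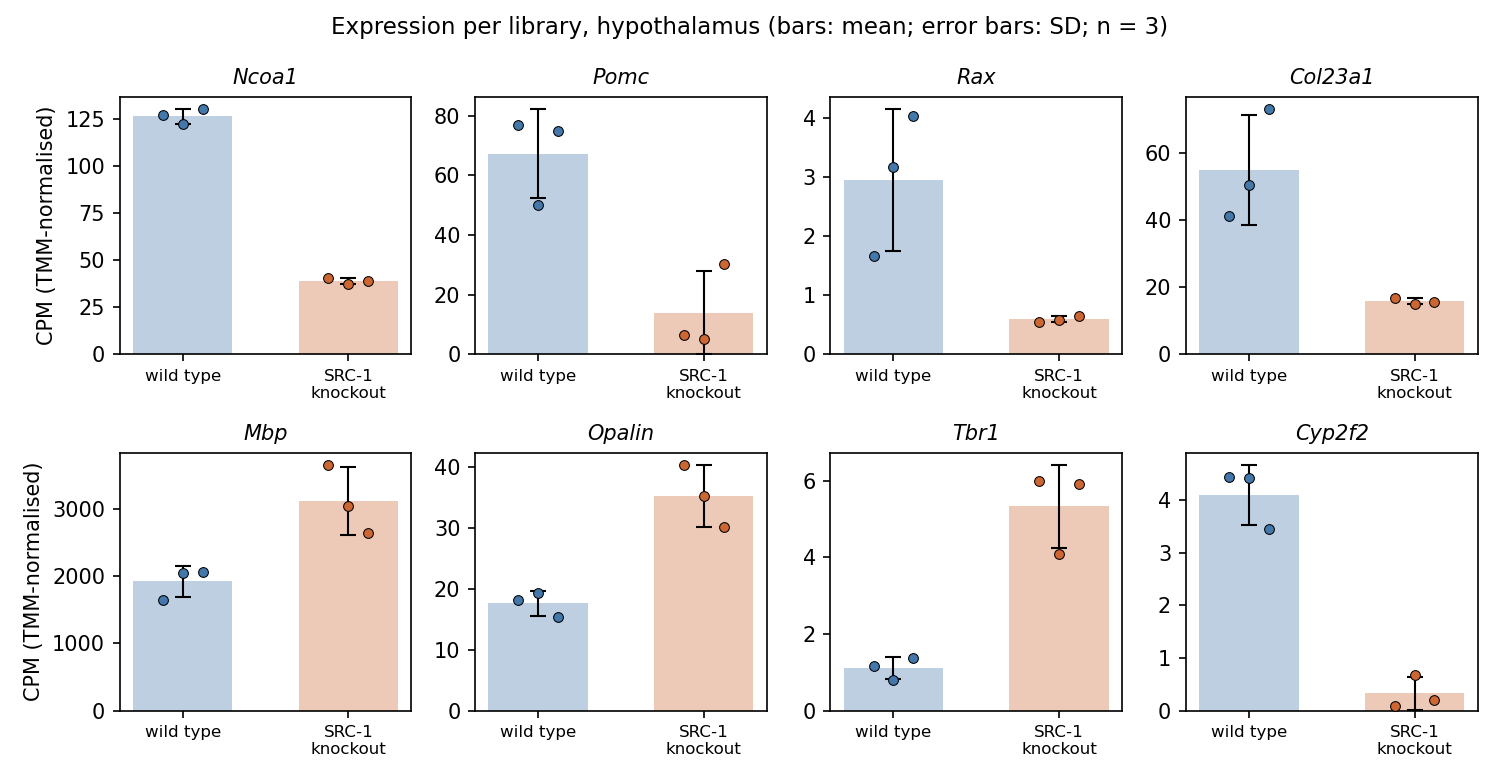
TMM-normalised CPM, counts scaled to library size (vertical axis), of 8 genes in the 3 wild-type and 3 SRC-1 knockout libraries, with points for libraries, bars for means and error bars for SD. Ncoa1, Rax, Col23a1, Cyp2f2, Mbp, Opalin and Tbr1 passed the test, and Pomc, whose knockout values spread widely, had an adjusted p of 0.375.

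Ependymal and tanycyte genes formed the group with the lowest camera p. Of the 22 tested members, 12 fell and none rose, 21 were lower when adjusted over the list alone, and all 22 log2 fold changes were negative, with a median of -1.3. Among those that fell were Gpr50, an orphan receptor of tanycytes (-1.51 ± 0.15), the Wnt antagonist Frzb (-1.32 ± 0.17) and the filament gene Vim (-0.80 ± 0.11). The camera adjusted p was 6e-21 with the preset correlation, and adjusted p = 0.128 with an estimated correlation. Fry's directional test gave an adjusted p of 0.0101. The mean log2 CPM over the list was 3.39, 3.40 and 3.51 in wild type and 1.97, 2.41 and 2.23 in the knockout. The number of falls was 6 without wild-type replicate 1 or 2, 7 without wild-type 3 or knockout 3, 3 without knockout 1, 6 with library totals alone, 8 with the stricter filter and 5 without the growth hormone pair.

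Lists for tissues beside the hypothalamus came next. In the pituitary list 1 of 9 members fell, 6 were lower when adjusted over the list alone, and the median was -1.2, also with Fshb, at 0 counts in the knockout, set to its bound. Pitx1, a transcription factor of the pituitary, fell (-3.70 ± 0.35), while Cga, the hormone alpha subunit, did not pass (adjusted p 0.056). Cga counts were 184, 225 and 502 in wild type and 15, 1 and 3 in the knockout, whereas Gh, growth hormone, had 477, 0 and 0 counts in wild type and 280, 7 and 1 in the knockout. The pituitary list had a camera adjusted p of 2.27e-06, or adjusted p = 0.298 with an estimated correlation. Meningeal fibroblast genes had a median of -1.6 with all 17 members negative, and Lum, a matrix proteoglycan, fell (-1.5 ± 0.28). The other 16 did not pass in edgeR, and 2 of the 17 were lower when adjusted over the list alone. DESeq2 called 7 of the 17, limma-voom 0 and limma-voom with sample quality weights 2. The camera adjusted p of the meningeal list was 7.77e-07, and adjusted p = 0.46 with an estimated correlation. The list mean was 3.54, 4.38 and 2.33 log2 CPM in wild type and 2.24, 2.32 and 2.22 in the knockout, and the median was -0.81 without wild-type replicate 2. Without wild-type 3 there were 5 falls, and without wild-type 1 or any 1 knockout library 0. Of 14 choroid plexus genes, Enpp2 alone passed in edgeR, and it rose (0.57 ± 0.10). This gene is also made by oligodendrocytes. The other 13 did not pass in edgeR, among them Folr1, a folate receptor, at -1.63 ± 0.32 (adjusted p 0.0519). DESeq2 called 5 of the 14, limma-voom 2 and limma-voom with sample quality weights 4. When adjusted over the list alone 1 was higher and 3 were lower. The list median was -0.55 and the camera adjusted p 0.00349, with adjusted p = 0.305 with an estimated correlation. With the stricter filter this list had a camera adjusted p of 0.0754. Enpp2 did not pass without wild-type 1, wild-type 3, knockout 1 or knockout 2, and 1 choroid plexus gene fell without wild-type 3 or knockout 2. The pituitary list held 2 falls without wild-type 3 or knockout 2. With the stricter filter it had 6 members, 0 falls and a median of -0.79, and with no filter 14 members, 3 falls and a median of -0.57. Its median was -0.8 without knockout 3.

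Myelin and oligodendrocyte genes were the group with the largest rise. Of 21 tested members, 7 rose and none fell, 19 were higher when adjusted over the list alone, and all 21 log2 fold changes were positive with a median of 0.67. Opalin, Aspa and Mbp were among those that rose, as were the claudin Cldn11 (0.53 ± 0.091), the tetraspanin Tspan2 (0.51 ± 0.085) and Cnp (0.54, from 318 to 463 CPM). The camera adjusted p was 4.05e-17, and adjusted p = 0.409 with an estimated correlation. The number of rises was 1 without wild-type replicate 1 or knockout 1, 3 without wild-type 3, 4 without knockout 2 and 13 without knockout 3, 1 with library totals alone, 2 with the stricter filter and 0 without the growth hormone pair. Of 14 genes of oligodendrocyte precursors, Bcas1 (0.68 ± 0.091) and Enpp6 rose, both genes of cells that are beginning to myelinate, and 4 were higher when adjusted over the list alone. That list had a median of 0.12 and a camera adjusted p of 0.00763, with adjusted p = 0.46 with an estimated correlation, and 0.0755 by camera without wild-type replicate 2. Its median was 0.05 without wild-type 2, 0.2 without wild-type 3 and 0.071 without knockout 1, with 1 rise without wild-type 1, wild-type 2 or knockout 1 and 3 without knockout 3.

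For lists with no member past the threshold over all genes, 4 numbers in brackets give the members at unadjusted p under 0.05, then those past the adjusted threshold with DESeq2, with limma-voom and with limma-voom using sample quality weights. Where no count adjusted over the list alone is given, it was 0 in both directions. Neuron markers had a median of 0.19 over 17 members (7, 5, 0 and 2), of which 7 were higher when adjusted over the list alone. The neurofilament genes Nefm (0.46 ± 0.094) and Nefh (0.43 ± 0.096) led it, with a camera adjusted p of 0.000453 and adjusted p = 0.409 with an estimated correlation. Astrocyte markers had a median of -0.023 over 16 members (7, 3, 0 and 1) with 2 higher and 1 lower when adjusted over the list alone, and did not pass camera (adjusted p 0.859). There was 1 rise in the neuron list without wild-type 2 or knockout 3, and 1 fall in the astrocyte list without wild-type 1. Nor did markers of microglia (median 0.063, adjusted p 0.0598; 4, 1, 0 and 0; 1 higher when adjusted over the list alone), of endothelium and pericytes (0.034, 0.27; 3, 1, 0 and 0), of blood cells (0.38, 0.174; 0, 0, 0 and 0) or of thalamus (0.10, 0.0518; 6, 1, 0 and 1). With 1 library left out, camera gave an adjusted p of 0.0398, 0.0494 and 0.00449 for microglia (wild-type 1, wild-type 3, knockout 2), 0.0238 for endothelium and 0.027 for blood cells (wild-type 2), and 0.0248 and 0.0419 for thalamus (knockout 1, knockout 3). In the striatal list, 1 of 19 members, Lrrc10b, fell (-0.90 ± 0.17), also when adjusted over the list alone, with a median of 0.038 and a camera adjusted p of 0.675, and 0 falls without any 1 library other than knockout replicate 3. In the list of cortex, hippocampus and amygdala, Tbr1 was the 1 rise of 19, also when adjusted over the list alone, and the list did not pass (median -0.058, adjusted p 0.892). The median, the mean and the camera direction differed in sign in 8 lists, none of them called. These were the striatal, cortical, astrocyte, coregulator, nuclear receptor, inhibitory synapse, monoamine and Alzheimer lists.

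Feeding and neuroendocrine genes were the next subject, since the arcuate nucleus and its neighbours make these peptides. Pomc, the precursor of the appetite-suppressing melanocortins, averaged 67.3 ± 15.0 CPM in wild type and 14.0 ± 14.0 CPM in the knockout (SD, n = 3 each), with a log2 fold change of -2.26 ± 0.81 and an adjusted p of 0.375. The appetite-promoting peptides Agrp (-2.0 ± 0.58, adjusted p 0.24) and Npy (-1.63 ± 0.68, adjusted p 0.444) did not pass either. Of the 26 genes of the focus panel Ncoa1 alone passed. Lateral hypothalamic Hcrt (0.47 ± 0.34) and Pmch (0.47 ± 0.32), Cartpt (-0.46 ± 0.27), Ghrh (-0.92 ± 0.47), Sst (-0.61 ± 0.25), Avp (-0.59 ± 0.78), Oxt (-0.66 ± 1.03), Crh (0.28 ± 0.36) and Trh (0.10 ± 0.45) did not pass, with adjusted p from 0.393 for Sst to 0.958 for Trh. Of the receptors and signal carriers, Lepr (-0.53 ± 0.22), Mc4r (-0.16 ± 0.26), Esr1 (-0.61 ± 0.35), Pgr (-0.09 ± 0.15), Nr3c1 (-0.09 ± 0.086) and Stat3 (-0.28 ± 0.070, adjusted p 0.104) did not pass. Gfap (-0.47 ± 0.44), C4b (-0.52 ± 0.29), Apoe (-0.31 ± 0.081, adjusted p 0.114), App (0.09 ± 0.081) and Bdnf (-0.02 ± 0.12) did not pass.

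Over the appetite peptide list of 20 genes (6, 2, 0 and 0) the median was -0.34 with 16 negative values, and none passed when adjusted over the list alone. Camera gave an adjusted p of 0.00394, and adjusted p = 0.46 with an estimated correlation. Without knockout replicate 1 the median was -0.22, and without knockout 3 there was 1 fall. In the neuroendocrine list Vgf, a granin, fell (-0.40 ± 0.077), 1 of 19 members, also when adjusted over the list alone. Its median was -0.35 and its camera adjusted p 0.00445, with adjusted p = 0.46 with an estimated correlation, and 0.149 by camera without knockout replicate 2. Without wild-type 1, wild-type 2 and knockout 2 the median was -0.16, -0.21 and -0.2, and Vgf did not pass with any 1 library left out. Melanocortin and leptin signalling held 2 falls among 25 members, the neuropeptide Y receptor Npy1r (-0.62 ± 0.12) and the transcription factor Foxo1 (-0.49 ± 0.094), with 6 lower when adjusted over the list alone. Its median was -0.096 and its camera adjusted p 0.00467, with adjusted p = 0.409 with an estimated correlation. The median was -0.052, -0.15, -0.059 and -0.15 without wild-type 1, wild-type 2, knockout 2 and knockout 3, and there were 0 falls without any 1 wild-type library or knockout 1 and 1 without knockout 2. Hypothalamic identity factors did not pass (median -0.20, adjusted p 0.223), with Rax the 1 fall of 28 and 2 lower when adjusted over the list alone. Without knockout 1 there were 0 falls and without wild-type 1 there were 2. Tshb stayed between 60 and 107 counts in the 6 libraries.

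Lists of hormone-responsive genes, nuclear receptors and coregulators were examined next. Whether SRC-1 acts on the genes of these lists was not tested. Glucocorticoid targets had a median of -0.51, and all 19 members were negative (7, 3, 0 and 1), with 5 lower when adjusted over the list alone. Map3k6 led with -0.87 ± 0.18 (adjusted p 0.0582). Camera gave an adjusted p of 2.22e-06, and adjusted p = 0.518 with an estimated correlation. The list means overlapped between the groups, at 4.48, 4.99 and 5.46 log2 CPM in wild type and 4.31, 4.42 and 4.56 in the knockout. The median was -0.22 without wild-type replicate 3, and there were 3 falls without wild-type 1. Estrogen and progesterone targets had a median of -0.28 over 14 members (5, 2, 0 and 3), 12 of them negative and 3 lower when adjusted over the list alone, with Cited1 at -1.23 ± 0.27 and Kiss1, kisspeptin, at -1.34 ± 0.39. The camera adjusted p was 0.00351, and adjusted p = 0.46 with an estimated correlation, and the median was -0.44 without wild-type replicate 2. Thyroid hormone targets held 3 falls among 16, with the hormone-binding Crym (-1.46 ± 0.24) and Fos among them, against a median of -0.031, and the list did not pass (adjusted p 0.351). By camera it had an adjusted p of 0.0223 without wild-type replicate 1, and 1 gene fell without knockout 1 or knockout 3. When adjusted over that list alone 2 were higher and 5 lower. Its members Crym and Dio2 are also on the ependymal list, and Fos is also on the list of immediate early genes. Insulin and growth factor signalling did not pass (median -0.022, adjusted p 0.0866), with Foxo1 the 1 fall of 26, also when adjusted over the list alone. By camera it had an adjusted p of 0.0213 without wild-type 3, with 2 falls, and of 0.0279 without knockout 1, and there were 0 falls without wild-type 1, wild-type 2, knockout 1 or knockout 2. Among 30 nuclear receptors Esrrg rose (0.58 ± 0.11), also when adjusted over the list alone, though not without any 1 wild-type library or knockout 1, and the list did not pass (median 0.028, adjusted p 0.884). Other coregulators did not pass (median -0.0051 over 22 members, adjusted p 0.52; 2, 1, 0 and 1), though Ppargc1a, at 0.39 ± 0.087, was higher when adjusted over the list alone.

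Immediate early genes are those that neurons induce on stimulation. Of 24 members, 5 of them positive, 3 fell, Fos (-1.51 ± 0.20), Egr1 (-1.14 ± 0.12) and Junb (-0.88 ± 0.14), and 7 were lower when adjusted over the list alone. The list median was -0.26 and the camera adjusted p 0.000104, with adjusted p = 0.46 with an estimated correlation. The median was -0.16 without wild-type replicate 2, and 1 gene fell without wild-type 1, knockout 1 or knockout 3. Genes of synaptic vesicles had a median of 0.097 over 24 members (5, 2, 0 and 1), led by Vamp1 (0.53 ± 0.11), the 1 higher when adjusted over the list alone. Their camera adjusted p was 0.00656, and adjusted p = 0.619 with an estimated correlation. Without wild-type replicate 2 it was 0.209 by camera (median 0.058), and without knockout replicate 1 it was 0.0853 (median 0.061). Excitatory synapse genes (median 0.05, adjusted p 0.0626; 5, 1, 0 and 0), inhibitory synapse genes (-0.001, 0.52; 5, 4, 0 and 1; 1 higher when adjusted over the list alone), monoamine genes (-0.0099, 0.846; 2, 0, 0 and 0) and the circadian clock (-0.043, 0.231; 5, 1, 0 and 1) did not pass camera. The excitatory list had an adjusted p of 0.00521 without wild-type 1 and 0.0385 without knockout 2. Without knockout 3 there was 1 rise among synaptic vesicle genes and 1 fall among inhibitory synapse genes. Of the clock genes 4 were lower when adjusted over the list alone, with Per2 at -0.36 ± 0.085.

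In the metabolic lists, Prdx6 was the 1 gene that passed over all genes. All 13 protein-coding mitochondrial transcripts were positive with a median of 0.20 (6, 3, 1 and 1), 3 of them higher when adjusted over the list alone, and ND2 stood at 0.44 ± 0.090. Camera gave an adjusted p of 4.06e-06, and adjusted p = 0.409 with an estimated correlation. Mitochondrial transcripts took 3.61% to 4.06% of counts in wild type and 4.22% to 4.43% in the knockout. Nuclear genes of oxidative phosphorylation had a median of 0.073, with 66 of 73 positive (1, 0, 0 and 0). Their camera adjusted p was 0.00019, and adjusted p = 0.695 with an estimated correlation. Ribosomal protein genes had a median of -0.088, with 74 of 76 negative (1, 0, 0 and 0), a camera adjusted p of 0.000117 and adjusted p = 0.695 with an estimated correlation. Glycolysis (median 0.095, adjusted p 0.0247; 3, 0, 0 and 0) and cholesterol synthesis (0.071, 0.0247; 2, 1, 0 and 0) both had adjusted p = 0.665 with an estimated correlation. Chaperones had a median of -0.11 (7, 0, 0 and 0), a camera adjusted p of 0.00124 and adjusted p = 0.46 with an estimated correlation. Lysosome and autophagy genes did not pass (0.00087, 0.892; 3, 1, 0 and 1), nor did antioxidant genes (-0.029, 0.81), where the peroxiredoxin Prdx6 fell (-0.43 ± 0.078), also when adjusted over the list alone, though not without wild-type 2, wild-type 3, knockout 1 or knockout 2. By camera, oxidative phosphorylation had an adjusted p of 0.221 without knockout replicate 3, and ribosomal proteins of 0.235 without wild-type replicate 3 and 0.064 without knockout replicate 2. The medians were 0.13 and 0.034 for oxidative phosphorylation without wild-type 3 and knockout 3, and -0.039, -0.056, -0.052 and -0.15 for ribosomal proteins without wild-type 3, knockout 1, knockout 2 and knockout 3. Glycolysis had 0.0917, 0.285, 0.0935 and 0.106 without wild-type 1, wild-type 2, knockout 1 and knockout 3, and cholesterol synthesis 0.263, 0.209 and 0.106 without wild-type 1, wild-type 2 and knockout 3, with medians of 0.037 and 0.13 without wild-type 2 and wild-type 3.

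Lists tied to ageing were included because the series concerns ageing and cognition. In the complement and immune list of 20 genes Lyz2, lysozyme, fell (-1.58 ± 0.25) and the alarmin Il33 rose (0.48 ± 0.086), each also when adjusted over the list alone. Its median was -0.23 and its camera adjusted p 0.00127, with adjusted p = 0.305 with an estimated correlation. Neither gene passed without wild-type 1 or knockout 1, nor Il33 without wild-type 2, and in place of 1 fall there were 2 without wild-type 3 and 0 without knockout 2 or knockout 3. Interferon-response genes had a median of -0.21 over 28 members (5, 0, 0 and 0), a camera adjusted p of 0.00796 and adjusted p = 0.665 with an estimated correlation. Extracellular matrix genes had a median of -0.13 over 29 members (7, 4, 0 and 2), 1 higher and 1 lower when adjusted over the list alone, led by Dcn (-1.60 ± 0.26), a camera adjusted p of 0.0125 and adjusted p = 0.573 with an estimated correlation. Of 10 senescence genes (3, 1, 0 and 0) 9 were negative and 2 lower when adjusted over the list alone, with a median of -0.13, a camera adjusted p of 0.0193 and adjusted p = 0.409 with an estimated correlation. Genes linked to Alzheimer disease did not pass (median 0.046 over 27 members, adjusted p 0.749; 5, 4, 0 and 3), with 1 higher and 4 lower when adjusted over the list alone. By camera, the interferon list had an adjusted p of 0.595 without wild-type replicate 2 and 0.0536 without knockout replicate 1, the matrix list 0.209 without wild-type replicate 2 and 0.0709 without knockout replicate 3, and the senescence list 0.165, 0.053 and 0.0515 without wild-type 3, knockout 1 and knockout 2. The median was -0.073 for the interferon list without wild-type 2, and -0.064 and -0.2 for the senescence list without wild-type 3 and wild-type 1. With no filter the senescence list had 20 members, 1 fall and a median of -0.47, and with the stricter filter 8 members and a median of -0.07. With no filter the complement list had a median of -0.45 with 4 falls and 1 rise. In the matrix list 1 gene fell without wild-type 2 or wild-type 3, and in the Alzheimer list 2 without wild-type 2. Dcn, Col1a1, Col1a2 and Col3a1 of the matrix list are also on the meningeal list.

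Of the 43 lists tested, camera called 24 with the preset correlation, 16 lower and 8 higher, and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05. Fry's directional test called 3, the ependymal, pituitary and choroid plexus lists, each with an adjusted p of 0.0101, and its mixed test called 24. With library totals alone there were 0 calls in the choroid plexus, complement, melanocortin, meningeal, insulin, nuclear receptor and striatal lists, and 1 each among immediate early genes, thyroid hormone targets and oligodendrocyte precursors. With the stricter filter there were 0 in those 7 lists and the neuroendocrine list, and 1 among precursors. With no filter, where 966 genes passed in all, some lists without a call as reported held several. These included 5 falls among glucocorticoid targets, 4 among Alzheimer genes and 3 each in the estrogen and interferon lists. Mitochondrial transcripts held 3 rises, while appetite peptides, oxidative phosphorylation and ribosomal proteins stayed at 0. Camera did not pass without the growth hormone pair for cholesterol synthesis (adjusted p 0.23), glycolysis (0.248) and precursors (0.052), nor for glycolysis with no filter (0.0546). It passed for thalamus with library totals alone (0.0247) and without the pair (0.0221), and for excitatory synapse without the pair (0.0213). The sex-linked list had 4 tested members, too few for a list test, with a median of 0.054.

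**Figure D2:**
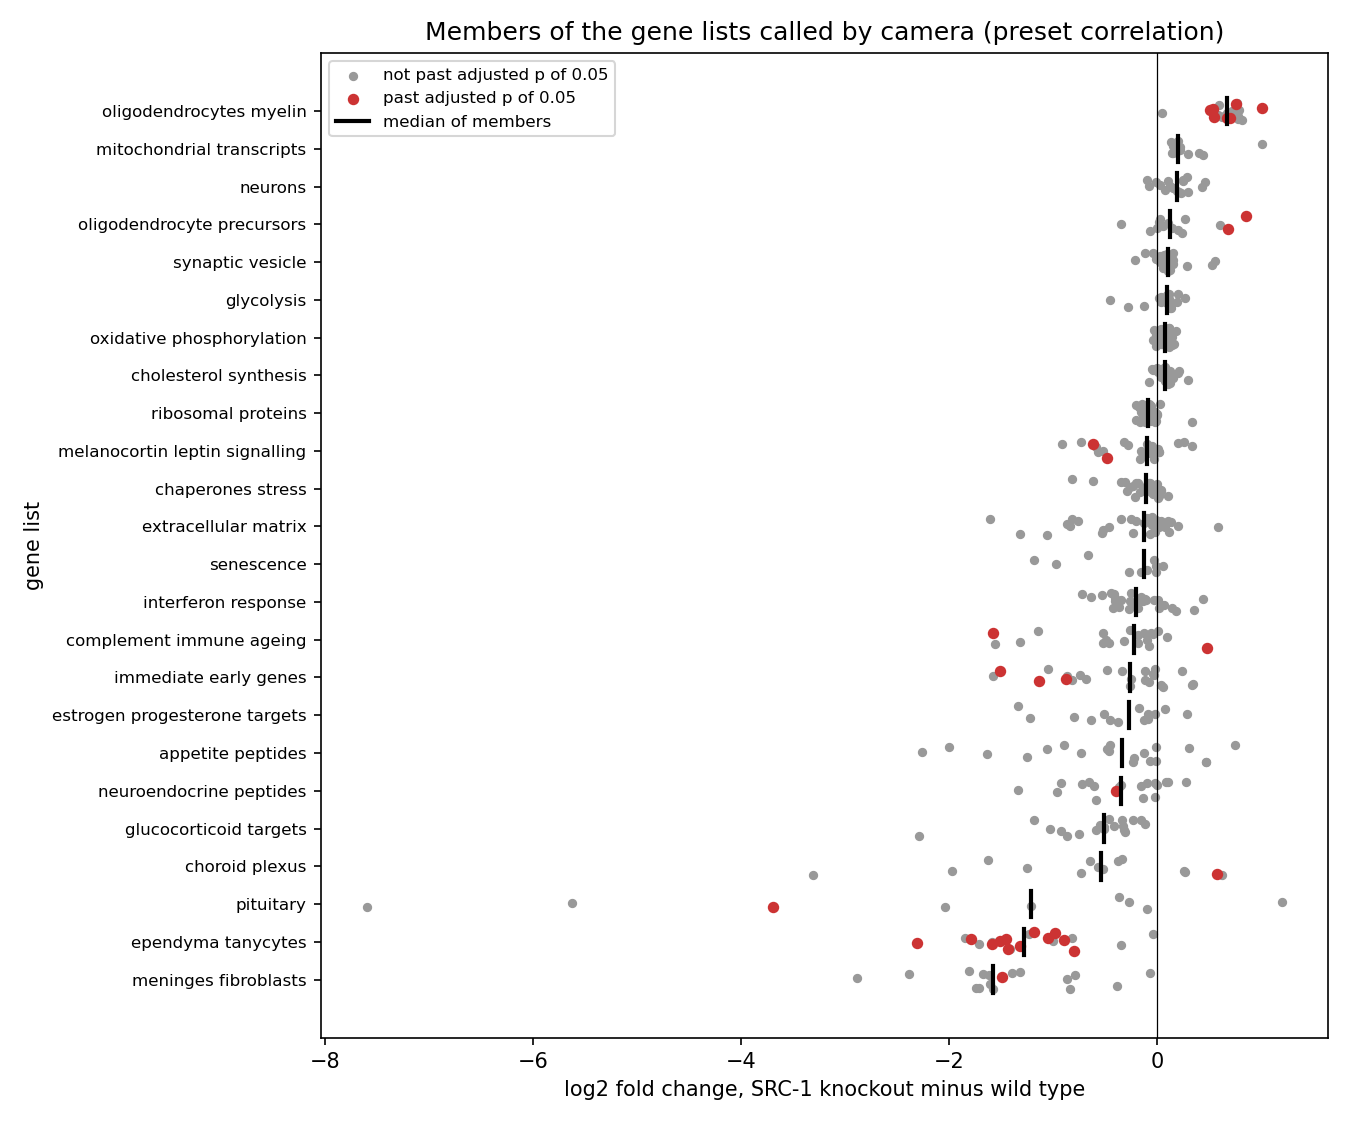
Log2 fold change, SRC-1 knockout minus wild type (horizontal axis), of every tested member of the 24 gene lists called by camera with the preset correlation (vertical axis). Each point is a gene, red where it passed the adjusted threshold, and black bars are list medians, which run from -1.6 for meningeal fibroblasts to 0.67 for myelin.

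The last comparison asked whether genes beside Ncoa1 changed more often than others, because a knockout made in one strain and crossed into another can keep donor DNA around the deleted gene. Within 10 Mb of Ncoa1, 0 of 72 genes passed edgeR's test (9 at unadjusted p under 0.05), against 168 of 20184 elsewhere (Fisher's exact test, two-sided, p = 1). By tool, DESeq2 called 4 of them, limma-voom 0 and limma-voom with sample quality weights 2. Pomc is itself a neighbour, with its last base at 4010643. Farther out, within 20 Mb, 8 of 133 genes had changed, 7 higher and 1 lower, or 6.02% against 0.795% elsewhere (odds ratio 7.98, 95% interval 3.32 to 16.6, Fisher's exact test, p = 1.54e-05). Fisher's test treats genes as independent, and the 7 higher ones lie close together, so its p and interval may overstate the evidence.

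The 7 that rose lay between 16282446 and 22080901 on chromosome 12 and were chosen for naming after their values were seen. Gm9282, Gm46313 and Gm3973 had 0 counts in every wild-type library and 307, 157 and 63 counts over the 3 knockout libraries. Against a floor of 3 counts over the wild-type group they were at least 98.6-fold, 50.3-fold and 20.2-fold higher, limits that cover counting error only. Gm38702 had 4 counts in wild type and 163 in the knockout, Gm40847 7 and 103, Gm48606 16 and 195, and Gm32719 35 and 195. Past 20 Mb, Adi1, whose last base is 28732174, rose as well. These 7 loci are uncertain as genes, since reads mapping to several places were not counted.

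**Figure D3:**
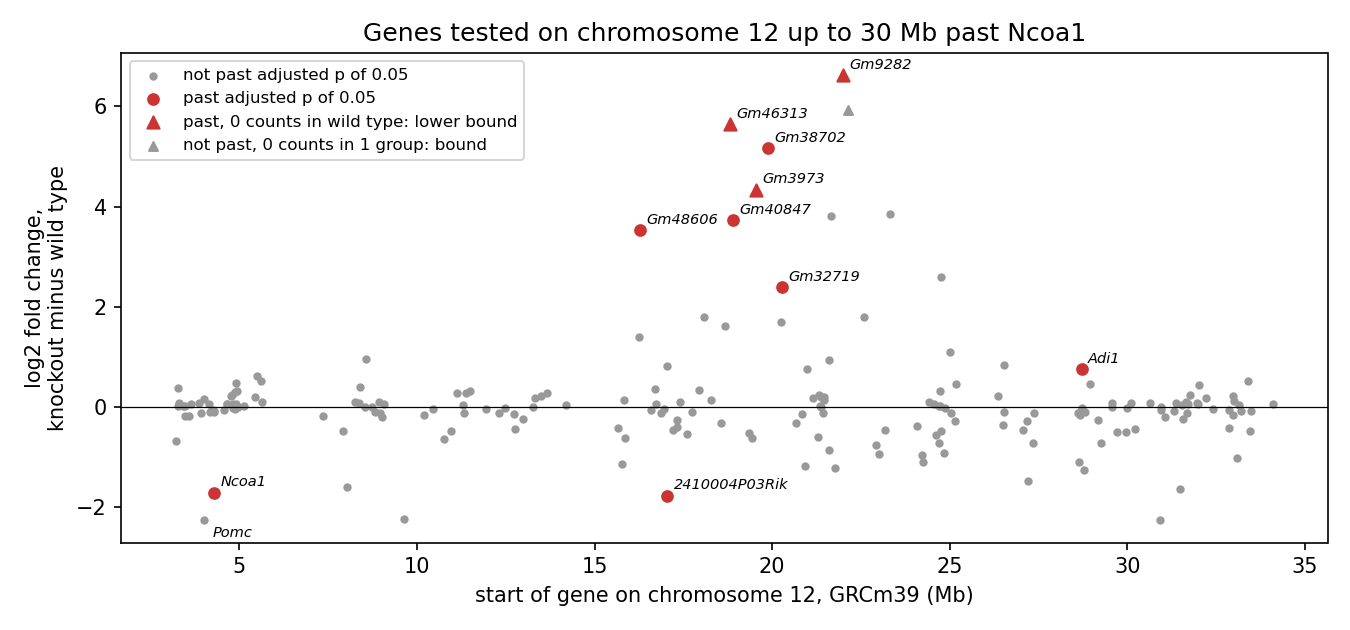
Log2 fold change, knockout minus wild type (vertical axis), of the genes tested on chromosome 12 up to 30 Mb past Ncoa1, by start position in Mb (horizontal axis, GRCm39). Red points passed the adjusted threshold and triangles mark bounds for genes with 0 counts in a group. Of the 8 rises shown, 7 gather between 16 and 23 Mb, and Adi1 lies farther out.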

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

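The log2 fold change of Ncoa1 stayed past the threshold in every alternative run, and all 169 calls kept their sign wherever the gene was tested. The number of genes changed, SRC-1 knockout against wild type, did not. It was 66 with library totals alone, 966 with no filter, 84 with at least 1 CPM in at least 3 libraries, 821 with DESeq2, 473 with limma-voom and sample quality weights, 480 at adjusted p under 0.10, and 88 at an absolute log2 fold change of at least 1. Without the 2 libraries with the most growth hormone counts, an alternative chosen after seeing the data with fewer samples, it was 29, of which 23 were among the 169. Leaving out 1 library gave 36 to 260, and 26 of the 169 passed in each of these 6 fits. The cause of the other differences was not tested.

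Of the 24 named rises and falls, 12 passed with library totals alone, 14 with the stricter filter, 4 without the growth hormone pair and 7 to 17 with 1 library left out. Tbr1, Opalin, Adi1 and Ncoa1 passed in all 6 leave-one-out fits. With the replicate number as a block 11 named genes and 155 genes in all passed, 93 of them shared with the 169. Deviations of same-numbered libraries correlated at -0.21, 0.35 and 0.22, and those of other pairs at -0.41 to 0.26. With 3 libraries per group these values do not decide whether the numbers pair the samples.

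Camera called 20 to 25 lists in the fits without 1 library, other scalings and filters, 0 with an estimated correlation and 3 with fry. For genes near Ncoa1, within 10 Mb, the odds ratio passed 1 with DESeq2 (4 genes, Fisher's exact test, p = 0.539), with quality weights (2 genes, p = 0.685) and without knockout replicate 3 (p = 0.521), the leave-one-out counts running from 0 to 1. In the 20 Mb window 8 genes had changed, and in the 30 Mb window, added after seeing the data, 9.

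Signs also turned for single genes and for medians of lists that were not called as reported. Some of these lists passed camera elsewhere, with an adjusted p of 0.0223 for thyroid hormone targets without wild-type replicate 1 and 0.0309 without the growth hormone pair, 0.027 for blood cells and 0.0238 for endothelium without wild-type 2, 0.00975 for blood cells with the block, and 0.0347 for monoamine genes without the pair. Leave-one-out ranges of log2 fold change were -0.046 to 0.022 for Ncoa2, -0.34 to 0.22 for Mc4r, -0.24 to 0.034 for Pgr, -1.70 to 0.18 for Oxt, -0.12 to 0.65 for Crh, -0.16 to 0.60 for Trh and -0.16 to 0.062 for Bdnf. Quality weights gave 0.0021 for Ncoa2, -0.036 for Trh and 0.030 for Bdnf, and dropping the growth hormone pair 0.091 for Mc4r, 0.019 for Pgr and 0.36 for Oxt. List medians ranged, with 1 library left out, from -0.048 to 0.016 for antioxidant genes, -0.052 to 0.017 for astrocytes, -0.011 to 0.78 for blood cells, -0.083 to 0.06 for cortex, -0.017 to 0.19 for endothelium, -0.072 to 0.063 for inhibitory synapse, -0.023 to 0.04 for lysosome, -0.063 to 0.069 for monoamine, -0.011 to 0.073 for nuclear receptors, -0.027 to 0.044 for coregulators, -0.012 to 0.076 for striatum and -0.28 to 0.086 for thyroid hormone targets. For lists not called as reported whose sign held, ranges were -0.32 to -0.095 for hypothalamic identity, 0.024 to 0.081 for excitatory synapse, -0.068 to -0.015 for the clock, 0.012 to 0.061 for Alzheimer genes, -0.05 to -0.007 for insulin signalling and 0.043 to 0.11 for microglia. With RLE the inhibitory synapse median was 0.00013. With library totals alone, where the median of all genes was -0.026, list medians were lower by about as much, at 0.043 for cholesterol synthesis and for oxidative phosphorylation, 0.016 for Alzheimer genes, 0.018 for excitatory synapse and 0.033 for microglia. The median was -0.0033 for endothelium, -0.03 for lysosome and -0.0017 for nuclear receptors. No filter gave 0.042 for blood cells, -0.16 for thyroid hormone targets (1 rise and 5 falls) and -1.5e-05 for lysosome, and the stricter filter -0.0023 for lysosome and -0.048 for striatum. The block gave 5e-04 for cortex and 0.0077 for inhibitory synapse. Dropping the growth hormone pair gave -0.06 for hypothalamic identity, -0.22 for appetite peptides, -0.23 for neuroendocrine peptides, -0.21 for matrix, -0.25 for thyroid hormone targets, 0.067 for precursors, 0.056 for glycolysis, 0.035 for cholesterol synthesis, 0.076 for inhibitory synapse, -0.0064 for lysosome and -0.031 for striatum. Low counts limit genes such as Gm3973, with 63 counts in all.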

Other observations

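The tests of scaling, library size, a general shift in cell types and further oligodendrocyte genes, and the counts of matching pseudogenes, were chosen after the results were seen, as were all of the added lists.

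An added list of 36 motile cilium genes was drawn up after the called genes were seen, and it holds none of them and none of the ependymal list. It leaves out called cilium genes such as Cfap52, Spag16 and Sntn, so its count over all genes says nothing of cilium genes in general. All 36 log2 fold changes were negative with a median of -0.86. With 0 members past edgeR's threshold over all genes, 32 had an unadjusted p under 0.05, 31 were lower when adjusted over the list alone, and DESeq2 called 24, limma-voom 4 and limma-voom with sample quality weights 10. Markers of arcuate neurons had a median of -0.92 with 15 of 17 negative (7, 4, 0 and 3, in brackets as in the lists above), ventromedial markers -0.38 with 11 of 12 negative (7, 3, 0 and 1), and anterior markers -0.59 with 10 of 15 negative (4, 0, 0 and 0). Markers of the lateral and posterior hypothalamus had a median of 0.35 with 10 of 13 positive (3, 1, 0 and 0). Their list mean was 3.57, 4.65 and 4.65 log2 CPM in wild type and 4.6, 4.75 and 4.6 in the knockout. Only wild-type replicate 1 lay apart, so this median rests on that library. The anterior list means also overlapped, at 3.51, 3.22 and 2.6 in wild type and 2.7, 2.29 and 3.12 in the knockout. None of these lists was tested with camera or for a difference between regions. When adjusted over the list alone, 3 arcuate and 3 ventromedial markers were lower, 0 anterior markers differed, and 1 lateral or posterior marker was higher and 1 lower. Txnip, which binds thioredoxin and responds to glucose, fell from 35.8 ± 3.47 to 17.1 ± 1.89 CPM (adjusted p 0.00392 in edgeR). On the log2 scale, Nnat fell by 0.70, Magel2 by 0.50 and Epcam by 3.55.

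The count of 169 genes was the highest of the 10 splits of the 6 libraries, reached by 1 split. The highest of the others gave 63, with wild-type 1, wild-type 2 and knockout 2 against the rest. The remaining splits gave 0 or 1. Splits of 3 against 3 are too few for a share under 0.05.

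The first pattern is the low level of ependymal and tanycyte genes in the knockout. A difference in scaling or depth would shift most genes alike. With library totals alone, the median log2 fold change of all genes was -0.026 against -1.3 for this list. Library totals set each library to the same sum, which tends to hold the median of all genes near 0. These values therefore show only that the list fell against other genes. A smaller piece of ventricle floor in the knockout blocks may lower ependyma, arcuate neurons and pituitary stalk together. Within groups, the ependymal and arcuate list means of the 6 libraries correlated at r = 0.39 (Spearman 0.60; permutation p 0.306 and 0.167, one-sided, 36 permutations; adjusted p 0.639 over 3 relations), and at 0.88 without the 2 farthest libraries, while ependyma against pituitary gave r = -0.043 (Spearman -0.086; permutation p 0.5 and 0.583; 0.43 without 2 libraries) and against myelin r = -0.38 (Spearman -0.31; p 0.639 and 0.667; -0.19). With 6 libraries these values do not decide, so dissection cannot be told apart from an effect of the genotype, which was not tested.

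The second pattern is the rise of 10 genes, 7 on chromosome 12 with starts from 16282446 (Gm48606) to 22004219 (Gm9282) and 3 elsewhere that are pseudogenes of genes on that chromosome. Gm2423 rose from 151 to 2478 counts over the group, Gm7993 from 40 to 647 and Rps7-ps3 from 226 to 741, and their closest coding genes are Ywhaq (99.7% identity), Odc1 (96.3%) and Rps7 (99.4%), all on chromosome 12 within 30 Mb of Ncoa1. Such a parent was found for 3 of 4 changed pseudogenes and 12 of 1137 others outside this part of the chromosome, in a search and a window set only after the changed ones had been seen, so these counts test nothing, while for the remaining one, Gm46386 on chromosome 13 (0 against 317 counts, at least 102-fold higher against a floor of 3 counts over the group), no parent was found. The coding genes Ywhaq, Odc1 and Rps7 did not themselves pass in edgeR. Their log2 fold changes were -0.115, -0.535 and -0.164 (adjusted p 0.622, 0.0516 and 0.499). Each of the 10 genes that rose had its highest count in knockout replicate 2, which had the lowest total of the knockout libraries. Counts in knockout replicates 1 to 3 were 543, 1150 and 785 for Gm2423 and 162, 286 and 199 for Gm7993. The cause of this difference within the knockout group was not tested. Library size could not account for a median fold of 15.5, since totals differed by at most 1.28-fold. The 10 genes were picked for a rise of over 1 on the log2 scale, so a fold above that ratio was fixed in advance. A strain variant on this part of chromosome 12, whose reads match the reference better elsewhere, may explain the rise and cannot be told apart from an effect of the genotype, which was not tested: the 12 unchanged pseudogenes with such parents had a median absolute log2 fold change of 0.329 against 0.248 for 760 others (permutation p 0.166, one-sided), a test that leaves out the changed ones and so decides nothing either way.

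The third pattern is the rise of myelin genes. A loss of ventricle floor tissue that raised all other cell types alike would lift neuron and astrocyte genes as much, but the myelin median lay 0.48 above that of neurons and 0.69 above that of astrocytes, where members had an SD of 0.16 and 0.26. More white matter or more oligodendrocytes in the knockout blocks may account for it. A median of 0 or less over 25 further oligodendrocyte genes was set to speak against this. Their median was 0.55, with 3 rises (Car2, Qdpr and Pllp) and 21 higher when adjusted over the list alone. Those 3 had passed before the list was drawn up, and the other 22 had a median of 0.53. All 25 were chosen after the myelin rise was seen, as genes of the same cell type. A positive median was therefore likely in advance, and it does not decide between these explanations. Whether the blocks or the animals differ stays open, and an effect of the genotype on oligodendrocytes was not tested.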
